A study of Mus musculus with 7 samples.

How the data were processed

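Messenger RNA was sequenced from mouse E14 embryonic stem cells carrying a light-inducible Brn2 cassette, at 0, 2, 4, 6, 14, 24 and 48 h of LED light at 300 µW, with 1 library per time point and 7 in all. Per the labels' protocols, RNA was taken with an RNeasy kit and libraries were made with a Lexogen SENSE kit. Reads were aligned to mm9 with Bowtie2, per the submitters' processing notes, which give no version. How reads were counted, whether strand was used, and whether transgene reads are among those of Pou3f2 are not given in the sources used here.

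The deposited values are 1 number per RefSeq transcript and library, and no header names their unit. They were checked by multiplying each value by a length and a library factor: with the genomic span (introns included), 83.1% to 84.3% of values between 2 and 20 reads lay within 0.1 of a whole read, against 20% by chance. The deposited signal therefore behaves as an RPKM per kilobase of span, and the log2 values, ratios and read numbers given here were computed from it. Read numbers are approximate because spans came from GRCm38 and not mm9; the reference served for names, lengths, overlaps and GC content, and no coordinates are given. The design had foreseen counts or normalized values, and the test for normalized values was used.

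The table holds 30673 rows, of which 3320 were transcription start site rows at 0 in every library and 27353 were transcripts. Left out were 695 further placements of a transcript and transcripts without a symbol. Symbols were matched by accession for 26930 rows, because the description column did not match the accession (12 of 346 olfactory receptor descriptions did); the name column gave the same gene in 14268 of 14798 rows. For 3668 of 20294 genes with more than 1 row, the row of highest mean was used. Of all genes, 4110 overlap another protein-coding gene.

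Trends were tested with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, on log2 of the value plus 1 against log2 of hours plus 1, over the 7 libraries with 5 residual degrees of freedom. A mean value of at least 1 was required, which left 6411 genes, and 11431 genes above 0 lay under it. The change given is the fitted log2 change from 0 to 48 h. A change was called at a Benjamini-Hochberg adjusted p under 0.05. The test takes the 7 libraries as independent points on a line, and no time point has a replicate. Lists were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative), and counts of members were also adjusted over the list alone. There were 31 gene lists, 29 of them with at least 3 tested members.

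Each later library was set against the 0 h library as a log2 ratio with 1 added, without a test, for genes with a value of at least 10 in either. The place of a list's median ratio was taken among 10000 random lists of the same size matched on mean expression. Principal components were taken from log2 values, and the first held 48.6% of the variance, or 41.0% with the GC trend removed.

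Named genes were Pou3f2, up to 12 called genes per direction with a mean of at least 10, up to 4 members of each described list with a mean of at least 5 and the largest fitted changes, 12 marker genes, and the 5 highest and 5 lowest genes of each ratio with a value of at least 20 in 1 library. Predicted genes and small RNAs were passed over, and not every gene this rule names is reported here. The gene lists, this rule, the tests and the alternatives named next were chosen before the data were examined. Alternatives were another normalization, filter, pseudocount, time scale, reference and list setting, and each library left out in turn.

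Chosen after seeing the data were the removal of GC and length trends, the fit without the 6 h and 48 h libraries, another choice of transcript row, and a limma-voom fit on recovered reads (at least 10 reads in at least 3 libraries, 13373 genes). From that last fit up to 12 genes per direction with a mean of at least 100 reads were named. The GC trend of a library was a natural spline with 5 degrees of freedom of each gene's deviation from its mean on transcript GC content, over 2447 genes of mean at least 5. GC content was known for 6386 of the 6411 tested genes (99.6%).

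The trend test was tested on simulated data of 6435 genes. Of genes changed 2-fold from 0 to 48 h, 26 of 67 were called, of those changed 4-fold 67 of 67, of those changed 8-fold 66 of 66, and 12 of 6236 unchanged genes were called. With a simulated GC trend, 67 of 6233 unchanged genes were called, or 16 with that trend removed. On simulated reads of 13584 genes, 25 of 67, 67 of 67 and 66 of 66 were called in the same order, with 7 of 13384 unchanged genes. The simulation gave every gene independent noise of the same spread, and its changes followed the fitted line in genes with enough reads. Libraries that share structure over genes were not simulated beyond the GC trend, so these rates need not hold for the real data. There, Ccnd1 had a fitted change of 3.57 and was not called by limma (adjusted p = 0.052). Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.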

Results

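Gene expression was measured by mRNA sequencing in E14 cells, a mouse embryonic stem cell line, grown in 2i, a medium with 2 kinase inhibitors that holds mouse stem cells in the naive state. The cells carried a cassette in which a light-switched transcription factor (GAVPO) drives Brn2 with a red fluorescent protein. Brn2, listed here as Pou3f2, is a POU-domain factor of neural progenitors and neurons. Cells were lit with an LED at 300 µW, and libraries were labelled 0, 2, 4, 6, 14, 24 and 48 h, with 1 library per time point, so no time point has a replicate and each time named here is the label of 1 library. The series asks how the transcriptome follows Brn2 induction. The depth implied by the values was 14.9, 7.62, 7.04, 13.7, 9.10, 9.96 and 16.1 M reads in order of time. The values behave as reads per kilobase of the whole genomic span, scaled to library size, which lowers the values of genes with long introns.

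Pou3f2, the induced gene, was already abundant in the library labelled 0 h, peaked at 14 h and was lowest at 48 h, with no trend with time that passed the test. Its value was 77.0 at 0 h, 36.9 at 2 h, 47.3 at 4 h, 96.2 at 6 h, 119 at 14 h, 41.3 at 24 h and 7.19 at 48 h, from about 6405 reads at 0 h and 649 at 48 h. The fitted log2 change from 0 to 48 h was -1.95 ± 1.05 (SE) and did not pass the limma test (adjusted p = 0.296). Without the 48 h library the slope over 0 to 24 h, scaled to 48 h, gave 0.10 (adjusted p = 0.988 by limma). The class III POU genes Pou3f1 and Pou3f4 were also lowest at 48 h. Pou3f1 stood at 270, 189, 446 and 18.0 at 0, 6, 14 and 48 h, and Pou3f4, highest at 6 h, at 36.7, 80.2, 55.4 and 3.71. Pou3f3 was far lower, between 0.426 and 1.33. It too was highest at 14 h, but it was lowest at 24 h and stood at 0.627 at 48 h. Neither Pou3f1 (adjusted p = 0.239) nor Pou3f4 (adjusted p = 0.296) passed the test. Whether the deposited values count the transgene, the endogenous gene or both is not given in the sources used here, so the direction of every trend below is against the labelled time and not against the measured level of Pou3f2.

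**Figure D1:**
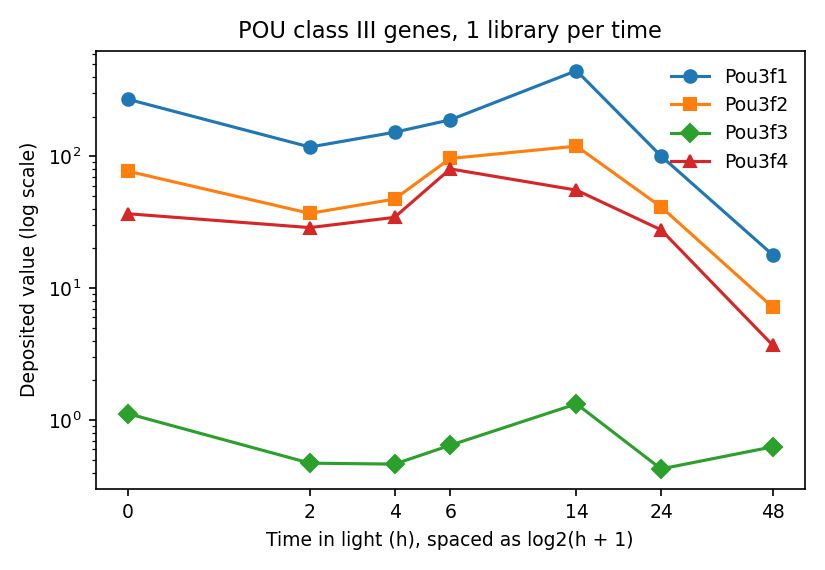
Deposited value (log axis) of Pou3f1, Pou3f2, Pou3f3 and Pou3f4 against labelled time in light, with 1 point per library and no error bars because each time has 1 library. Pou3f2 peaks at 119 at 14 h and is lowest at 48 h, at 7.19.

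Several genes of neuronal differentiation rose with time in the main test, with calls that depend on single libraries and settings, as given below. Neurod1, a proneural basic helix-loop-helix factor, went from 3.65 at 0 h to 22.4 at 14 h, 60.7 at 24 h and 43.6 at 48 h (fitted log2 change 4.51 ± 0.75 SE, adjusted p = 0.041). Insm1, a zinc-finger factor of neuronal precursors, was 0.245 at 0 h and 0.145 at 6 h, and then 5.60, 16.3 and 28.2 at 14, 24 and 48 h (5.28, adjusted p = 0.049). The Notch ligand Dll1 (0.079 to 3.17, adjusted p = 0.036) and Crmp1, a protein of growth cones (0.109 to 4.29, adjusted p = 0.041), rose as well. Sox3, a SoxB1 factor of neural progenitors, had the lowest adjusted p of all genes (0.004) and was higher in each later library than in the one before, from 0.716 at 0 h to 17.2 at 48 h. The step from 4 h (2.89) to 6 h (2.90) was slight, and only about 22 and 18 reads were counted at 0 and 2 h. Of the 11 tested members of the proneural and neuronal list, all had a positive fitted change and 4 rose, or 9 adjusted over the list alone; the median fitted log2 change was 1.94. The list was called up by camera with a preset correlation (adjusted p = 2.9e-08) and was not called with an estimated correlation (adjusted p = 0.359). Tubb3, neuronal beta-tubulin, was at 5.40 at 0 h, between 10.3 and 13.5 from 2 to 24 h and 44.6 at 48 h, and did not pass (adjusted p = 0.128). Neurod1 lies inside the span of Cerkl and Crmp1 overlaps Evc, and reads of overlapping genes may be counted for both.

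**Figure D2:**
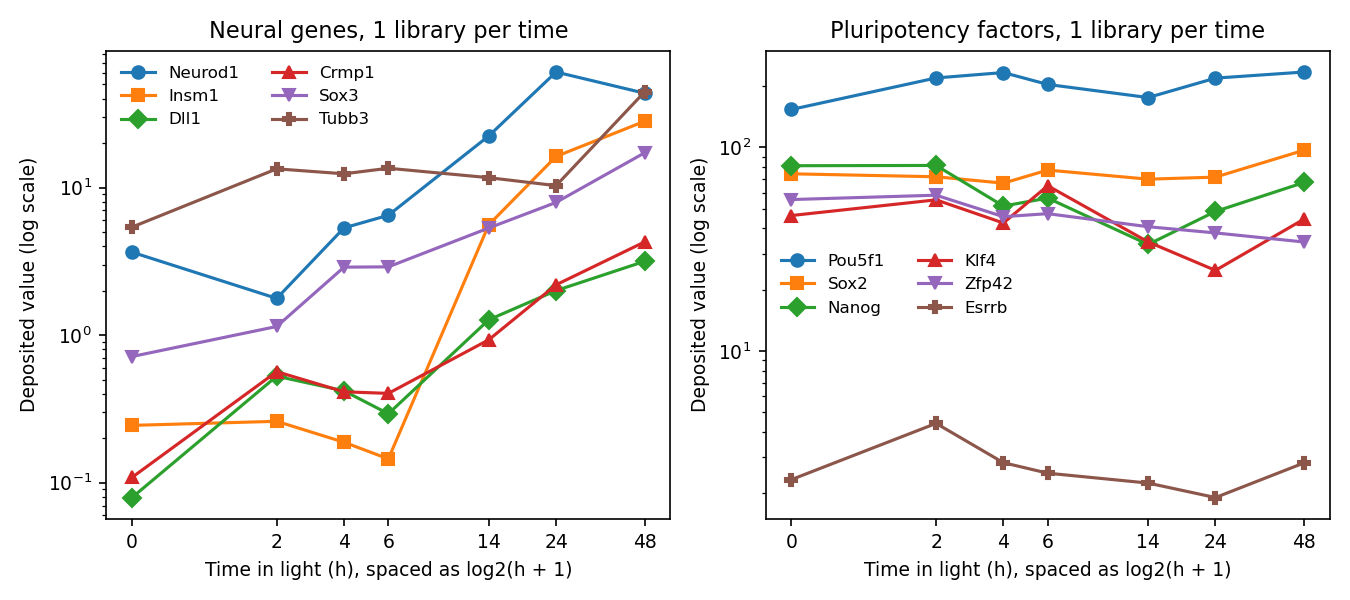
Deposited value (log axis) of 6 neural genes (left) and 6 pluripotency factors (right) against labelled time in light, 1 point per library. Insm1 goes from 0.145 at 6 h to 28.2 at 48 h, while Pou5f1 stays between 154 and 235.

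In the limma trend test, 19 of 6411 genes rose and 4 fell with time at an adjusted p under 0.05, and 1381 had an unadjusted p under 0.05. Those with a mean value of at least 10 were Neurod1, Pcbp4 (an RNA-binding protein, 3.82 to 24.1, adjusted p = 0.036) and Nt5dc2 (8.07 to 32.2, adjusted p = 0.036) among the rising genes, and Eif4a2 among the falling ones (a translation initiation helicase, 36.3 to 10.9, adjusted p = 0.036). Pcbp4 overlaps Gpr62, Nt5dc2 overlaps Stab1 and Eif4a2 overlaps Rfc4, so their reads may be shared in the same way. The other called genes have means under 10 and were named after their values were seen. The falling ones were Slc38a4 (an amino acid transporter, 5.47 to 0.603), Aard (6.53 to 0.761) and Ccdc117 (6.00 to 1.82), and the rising ones included Prph, the neuronal filament peripherin (0.459 to 6.04), and F2rl1, a protease-activated receptor (2.42 to 15.3). The count rests on single libraries: it was 1 rising and 0 falling without the 4 h library, 1 and 0 without the 24 h library, 1 and 1 without the 48 h library, 7 and 2 without the 2 h library, and 54 and 25 without the 0 h library. Of the 23 calls, neuronal genes included, 1 was kept without the 4 h, the 24 h or the 48 h library, and 13 without the 0 h library. With quantile normalization 1 was kept, and with pseudocount 5 or no filter on low values 0. The libraries also differed in a property tied to GC content: relative to gene means, the median of the 10% of genes with the highest GC content was 0.44 (log2) at 48 h and -0.26 at 0 h. With this trend removed from each library, 11 genes rose and 2 fell, and 10 of the 23 calls were kept. Neurod1 (adjusted p = 0.038) and Sox3 (fitted change from 3.40 to 2.83, adjusted p = 0.038) kept their calls. Of the 4 called genes with a mean of at least 10, Neurod1 was the one that did: Pcbp4 went from 2.17 to 1.59 (adjusted p = 0.065) and Nt5dc2 from 1.70 to 1.38 (adjusted p = 0.057). The fitted change of Insm1 went from 5.28 ± 0.92 (SE) to 4.90 ± 0.95 (adjusted p = 0.066) and that of Crmp1 from 2.11 ± 0.35 to 2.00 ± 0.34 (adjusted p = 0.064). That of Eif4a2 went from -1.69 ± 0.26 to -0.86 ± 0.27 (adjusted p = 0.162).

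**Figure D3:**
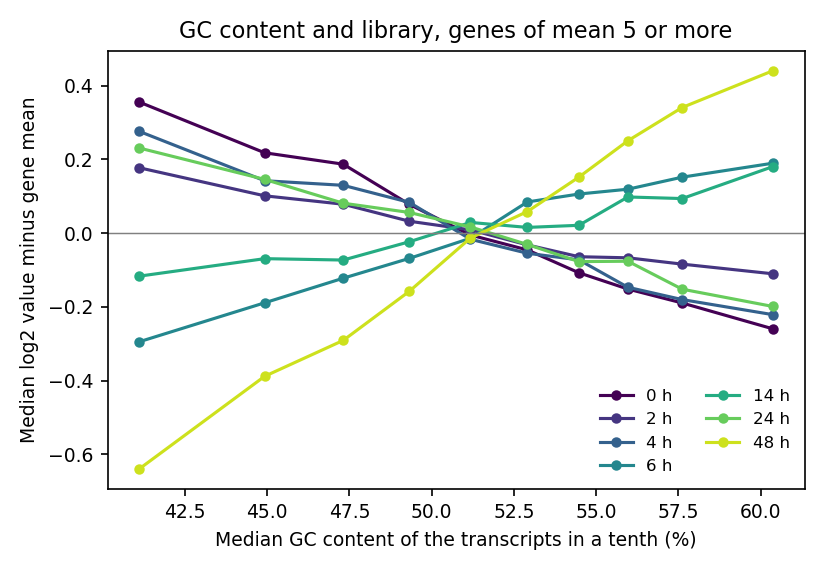
Median log2 value minus the gene's mean over the libraries (y axis) for genes of mean 5 or more, in 10 equal groups by the GC content of their transcripts (x axis, percent), 1 line per library. The 48 h line goes from -0.64 in the lowest group to 0.44 in the highest, and the 0 h line from 0.36 to -0.26.

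Of the genes above 0, 11431 lay below the mean value of 1 that the trend test required. A limma-voom fit on the reads recovered from the values, chosen after seeing the data, tested 13373 genes, of which 291 rose and 108 fell, and 323 rose and 54 fell with the GC trend removed. Unadjusted p was under 0.05 for 3156 genes, or 2642 with that trend removed. The check on reordered libraries given below covers the main test and not this fit, so its calls have no such check. All 23 genes called above were called in this fit. Genes named below that did not pass in the main test but rose on reads included Ccnd1 (adjusted p = 0.011), Sox4 (adjusted p = 0.012), Hes6 (adjusted p = 0.031), Utf1 (adjusted p = 0.031) and Lefty2 (adjusted p = 0.037). Those that fell on reads included Dppa2 (adjusted p = 0.035), Mdm2 (adjusted p = 0.033), Hsp90aa1 (adjusted p = 0.031) and Dnajb9 (adjusted p = 0.0495). With the GC trend removed Ccnd1, Sox4 and Lefty2 were still called on reads (adjusted p = 0.015, 0.016 and 0.048 in that order). Hes6, Utf1, Dppa2, Mdm2, Hsp90aa1 and Dnajb9 were not (adjusted p = 0.096, 0.085, 0.104, 0.066, 0.068 and 0.107 in that order). The 12 rising genes with the largest fitted changes and a mean of at least 100 reads were led by Gfra3, a receptor of the GDNF family (log2 change 10.99, adjusted p = 0.004), and Insm1 (10.1, adjusted p = 0.006). They also held Nhlh1 and Ebf3, neuronal transcription factors (8.05 and 8.04), Cadm3, a neuronal adhesion molecule (7.32), Igfbpl1 (6.62) and Lefty1, a Nodal antagonist (7.83). The remainder were Col1a2, a fibrillar collagen (9.34), Lamb3, a laminin chain (8.45), Serping1, the C1 inhibitor (7.51), Mfap4, a microfibril protein (6.91), and Cyp1b1 (6.44 ± 1.54 SE, and with the GC trend removed 6.93 ± 1.63, adjusted p = 0.050, not called). Lamb3 overlaps G0s2, for which about 490 reads were counted at 48 h against 642 for Lamb3, so reads of G0s2 may be among them. A fitted change follows a straight line and is not the observed ratio of 48 h to 0 h. It can exceed that ratio in genes that rise late. Gfra3 went from 0.022 at 0 h to 4.71 at 48 h. It had about 10, 4, 6 and 10 reads at 0, 2, 4 and 6 h. Insm1 went from 0.245 to 28.2, with about 11, 6, 4 and 6 reads at those first times. For Nhlh1 about 6 reads were counted at 14 h, 55 at 24 h and 1026 at 48 h. Map2, the dendritic microtubule protein, rose from 0.008 to 0.116 (log2 change 3.75, adjusted p = 0.008). Of 26 neuronal list members tested on reads, 13 rose and 0 fell, or 22 rose adjusted over the list alone. The fibroblast and feeder list, with 3 members in the main test and 9 on reads, was called up on reads (median 0.61, adjusted p = 0.024). With the GC trend removed its median was 0.53 and the call was lost (adjusted p = 0.060).

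Among the genes falling on reads with a mean of at least 100 reads, Stra8, a retinoic acid-induced gene of germ cells entering meiosis, had the largest change: 1.99 at 0 h, 0.536 at 2 h, 0.137 at 14 h and 0.037 at 48 h (log2 change -5.48, adjusted p = 0.001). It was followed by S100a13 (-3.78), Slc38a4 (-3.44), Calcoco2, an autophagy receptor (-3.41), Mcidas, a regulator of multiciliated cells (-3.41), and Ddit3, the stress factor CHOP (-3.39). Cd84, Aard, H2-Bl and the desmosomal gene Dsp fell as well, by 3.01, 2.85, 2.76 and 2.71 on the log2 scale. Ifit1bl2 and Gca fell by 2.93 and 2.50, and with the GC trend removed their changes were -2.19 and -1.52 and neither was called (adjusted p = 0.113 and 0.055).

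Pluripotency factors were still present at 48 h. Pou5f1 was 154 at 0 h, 220, 233, 204, 176 and 219 at 2, 4, 6, 14 and 24 h, and 235 at 48 h, and Sox2 lay between 66.8 and 97.0 (adjusted p = 0.449 and 0.592). Nanog was 81.4 at 0 h, 81.6 at 2 h, 51.6 at 4 h, 56.4 at 6 h, 33.4 at 14 h, 48.5 at 24 h and 67.3 at 48 h (adjusted p = 0.375). Klf4 ran from 46.3 at 0 h through 55.3, 42.6, 64.9, 34.4 and 24.9 to 44.5 at 48 h (adjusted p = 0.420), and Zfp42 through 55.5, 58.3, 45.7, 47.3, 40.8, 38.0 and 34.3 (adjusted p = 0.138). Esrrb, whose gene is long, lay between 1.91 and 4.41. Of 23 tested members of the naive pluripotency list, 1 rose, the homeobox gene Gbx2 (1.42 to 27.9, adjusted p = 0.041), and 0 fell, or 1 rose and 1 fell adjusted over the list alone. With the GC trend removed the change of Gbx2 went from 3.15 to 2.72 and was not called (adjusted p = 0.065), while on reads it was called with and without that trend (adjusted p = 0.015 and 0.006). Dppa2 (23.9 to 7.30, adjusted p = 0.072) and Sall4 (13.3 to 25.2) did not pass, and the list was not called (median -0.18, adjusted p = 0.434). Neural progenitor genes were uneven. Sox1 lay between 0.473 and 1.72, Nes between 1.29 and 2.49 and Pax6 at or below 0.072 in every library. The neural progenitor list (13 tested, 1 rose, Sox3; median 0.55, adjusted p = 0.034) was not called with the GC trend removed (median 0.25, adjusted p = 0.322) and had an adjusted p = 0.542 with an estimated correlation. It was not called without the 48 h library either (median 0.019, adjusted p = 0.116). Its members Vim (26.1 to 77.3), Sox21 (29.3 to 36.5) and Pou3f4 (36.7 to 3.71) did not pass.

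Formative and primed pluripotency genes were called up as a list (15 tested, 3 rose, or 6 adjusted over the list alone; median 0.65, adjusted p = 3.3e-04). The list had a median of 0.33 with the GC trend removed (adjusted p = 0.031) and an adjusted p = 0.359 with an estimated correlation. The 3 were Sox3, Otx2, a homeobox factor of the epiblast (1.30 to 9.01, adjusted p = 0.036), and the tight-junction gene Cldn6 (2.14 to 18.5, adjusted p = 0.036), while Sox4 (1.05 to 29.2, adjusted p = 0.062) did not pass, nor did Pou3f1, the member of this list named here with a negative fitted change (-2.44, adjusted p = 0.239). With the GC trend removed Otx2 kept its call and Cldn6 did not (2.52 to 2.36, adjusted p = 0.057). The Notch pathway list was called up (11 tested, 1 rose, Dll1, or 4 adjusted over the list alone; median 0.57, adjusted p = 0.002, and 0.601 without the 48 h library) with Hes6, an inhibitor of Hes1, at 6.38 at 0 h, 46.9 at 14 h and 32.0 at 48 h (adjusted p = 0.062), Rfng at 6.82 and 39.4 at 0 and 48 h, and Hes1 between 18.8 and 33.2. The Notch call was lost at an adjusted p = 0.553 with an estimated correlation. Dll1 also belongs to the proneural and neuronal list, so the calls of these lists are not independent. Cholesterol biosynthesis genes were called up with no single call (26 tested, 22 with a positive change, 0 called over all genes and 4 adjusted over the list alone; median 0.63, adjusted p = 1.0e-04, but adjusted p = 0.610 with an estimated correlation). The list also holds fatty acid genes: the desaturases Scd2 (56.1 to 176) and Scd1 (22.9 to 54.4) and the fatty acid synthase Fasn (14.4 to 39.2). These and Tmem97 (9.26 to 21.9) had the largest fitted changes among its members with a mean of at least 5, and did not pass alone. Replication-dependent histones had a positive fitted change in 27 of 28 members, with 0 called over all genes or adjusted over the list alone. That list was called up (median 0.86, adjusted p = 1.4e-05), and was not called without the 0 h library (adjusted p = 0.58). Its median was 0.49 with the GC trend removed (adjusted p = 0.007), and the call was lost at an adjusted p = 0.553 with an estimated correlation. H3c4 was 1.97 at 0 h and 8.31 at 48 h, and H3c6 2.29 and 9.21. These values rest on few reads, about 37 and 168 for H3c4 and 29 and 124 for H3c6. The core pluripotency list was called up (14 tested, 0 called over all genes, 3 up and 1 down adjusted over the list alone; median 0.36, adjusted p = 0.027), with Utf1 at 28.7 and 364, Lin28a at 1.99 and 11.96 and Rif1 at 15.6 and 4.38 at 0 and 48 h, and lost its call with the GC trend removed (median 0.30, adjusted p = 0.052), without the 0 h, 24 h or 48 h library (adjusted p = 0.108, 0.052 and 0.057) and at an adjusted p = 0.553 with an estimated correlation.

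The p53, oxidative stress and heat shock lists were called down, with 0 members called over all genes. In the p53 response, 18 of 21 tested members had a negative fitted change and 1 fell adjusted over the list alone (median -0.52, adjusted p = 0.002, but 0.060 without the 24 h library, and adjusted p = 0.684 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, was 16.2 at 0 h, 22.1 at 4 h and 4.00 at 48 h (adjusted p = 0.078), Plk2 24.1, 36.3 and 9.52, Trp53inp1 22.0, 25.6 and 7.50, and Ccng1 142, 131 and 39.8. With the GC trend removed the log2 ratio of 48 h to 0 h went from -1.78 to -1.32 for Mdm2, from -1.25 to -0.92 for Plk2, from -1.44 to -0.23 for Trp53inp1 and from -1.81 to -0.72 for Ccng1. The p53 list as a whole was still called down by camera with that trend removed, at the preset correlation (median fitted change -0.67, adjusted p = 1.3e-05). In the oxidative stress list of Nrf2 targets, 13 of 15 had a negative change and 1 fell adjusted over the list alone (median -0.64, adjusted p = 0.010, but adjusted p = 0.684 with an estimated correlation). With the GC trend removed the median of the oxidative stress list was -0.47 (adjusted p = 0.004 by camera at the preset correlation). Hmox1, heme oxygenase, was 58.0 at 0 h, 139 at 4 h, 150 at 6 h, 18.9 at 14 h and 12.46 at 48 h (adjusted p = 0.177), and Srxn1, Gclm and Nqo1 stood at 24.2, 17.9 and 13.9 at 0 h and at 7.97, 4.71 and 6.93 at 48 h. Heat shock genes were called down (16 tested, 1 fell adjusted over the list alone, median -0.61, adjusted p = 0.032, but 0.054 without the 2 h library and 0.078 without the 48 h library), with Hsp90aa1 at 999 and 304 and Hspe1 at 78.1 and 19.2 at 0 and 48 h. The heat shock median was -0.32 with the GC trend removed (adjusted p = 0.011), and the call was lost at an adjusted p = 0.542 with an estimated correlation. Hspe1 overlaps Hspd1 (63.5 and 28.9), and Hsph1 was at 14.1 and 5.66. The integrated stress and unfolded protein list was not called (23 tested, 2 fell adjusted over the list alone, median -0.38, adjusted p = 0.085, or adjusted p = 0.684 with an estimated correlation). It was called down with the GC trend removed (-0.49, adjusted p = 2.7e-04) and with quantile normalization (-0.46, adjusted p = 0.024), among other settings. Among its members, Ddit3 was at 14.6 and 1.78, Trib3 at 10.9 and 3.79, Nupr1 at 14.7 and 4.73, and Dnajb9 at 9.76 and 1.43 at 0 and 48 h. None of the 10 called lists held with an estimated correlation, where the adjusted p was 0.359 or more.

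Of the 29 lists with at least 3 tested members, 19 were not called. By median fitted log2 change these were the Wnt (0.75), fibroblast and feeder (0.47), FGF and ERK (0.35), BMP and SMAD (0.34), glycolysis and hypoxia (0.31), endoderm (0.30), neural crest (0.26), interferon (0.07) and ribosomal protein (0.05) lists above 0. Below 0 lay the G1/S (-0.03), immediate early (-0.05), housekeeping (-0.07), trophectoderm (-0.10), apoptosis (-0.15), circadian (-0.17), naive pluripotency (-0.18), POU family (-0.20) and G2 and mitosis (-0.28) lists, and the integrated stress list (-0.38). For neural crest and housekeeping the test pointed the other way from the median, as it did for trophectoderm. Mesoderm and 2-cell-like lists had fewer than 3 members with a mean of at least 1.

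Many gene lists had higher medians at 2 h than at 0 h, growth-factor response lists among them, with 1 library on each side and no test. Trh, the thyrotropin-releasing hormone gene, was 6.16 at 0 h and 67.0 at 2 h, Utf1 28.7 and 152, the corepressor Rcor2 6.57 and 25.3, the histone gene H2bc18 5.74 and 20.01, and Gadd45b 11.1 and 35.4. For H2bc18 only about 33 and 58 reads were counted. The medians of the FGF and ERK list (log2 ratio 0.61 over 12 genes) and of the immediate early list (0.57) lay above all 10000 random lists matched on mean expression, as did the BMP and SMAD list (0.79), where Id1 was 0.828 and 11.2, Id2 1.17 and 7.27, Id3 9.46 and 27.9, and Lefty2 1.91 and 4.28. Dusp6, a phosphatase induced by ERK, was 2.38 and 8.57 and Ccnd1, cyclin D1, 2.10 and 12.3, while Spry2 was 13.2 and 9.70 and Etv5 9.30 and 12.01. The Wnt (0.98) and trophectoderm (1.31) lists, which share Bmp4, Id2 or Ccnd1 with those lists, stood at the same place, as did glycolysis and hypoxia (0.60), with Slc2a1 at 5.67 and 12.1 and Slc2a3 at 44.3 and 82.7. So did replication-dependent histones (0.72) and the Notch list (0.41), and the proneural and neuronal (0.48, percentile 99.99) and neural progenitor lists (0.32, percentile 99.93) stood close to it. The FGF and ERK median against 0 h was also above all random lists at 4, 6, 14 and 24 h, at 0.78, 0.77, 0.82 and 0.54, and was 0.39 at 48 h (percentile 95.2). G2 and mitosis genes were lower than all random lists (-0.37). The 5 genes lowest at 2 h against 0 h were Cited4 (33.7 and 2.51), the surface antigen Ly6a (29.1 and 3.12), Zfp488 (158 and 38.0), D1Pas1 (25.2 and 6.62) and Olfr613 (47.4 and 13.4).

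At 2 h, 54 genes were at least 2-fold higher and 26 lower than at 0 h, among 1432 with a value of at least 10 in either library and with 1 added to both. At 4 h the counts were 25 and 9, and at 6 h 88 and 25, or 47 and 5 with the GC trend removed. Trh and Utf1 led at both times, at 49.5 and 106 at 4 h and 38.6 and 168 at 6 h. They were followed by the imprinted gene Phlda2 (12.2 at 0 h, 39.3 and 46.3), by Zfp36l1 (9.27 and 25.8) and Tmsb4x (21.8 and 55.7) at 4 h, and by Rpl32l (25.01 and 126) and Mif (322 and 1144) at 6 h. Ly6a was again low (4.502 and 6.53), as was Zfp488 (76.8 and 64.6), with Cited4 (6.55), D1Pas1 (9.38) and osteopontin, Spp1 (36.1 and 16.2), at 4 h and Hspe1 (29.4), Rpl22l1 (31.2 and 12.4) and Olfr613 (21.2) at 6 h. After removal of the GC trend the 6 h log2 ratio of Rpl22l1 went from -1.27 to -0.62 and that of Olfr613 from -1.13 to -0.20, so neither was 2-fold lower.

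At 14 h (59 genes higher, 48 lower) the highest were Hes6 (log2 ratio 2.70), Neurod1 (2.33), Scd2 (1.94), Utf1 (1.91) and Id3 (1.80). The lowest were Ly6a (29.1 and 1.15), the aquaglyceroporin gene Aqp3 (48.8 and 4.25), Plk2 (24.1 and 5.45), Ccng1 (142 and 37.7) and Trp53inp1 (22.0 and 5.23). At 24 h (70 and 35) Neurod1 (3.73), Ccnd1 (3.52), Trh (3.10), Hes6 (2.54) and Utf1 (2.47) were highest. Ly6a (1.21), Aqp3 (3.26), the germline gene Tex19.1 (116 and 22.1), Hmox1 (11.7) and Plk2 (6.70) were lowest. At 48 h 257 genes were at least 2-fold higher and 126 lower, or 154 and 42 with the GC trend removed. Trh reached 232 (log2 ratio 5.03), Insm1 28.2 (4.55), G0s2, which lies within Lamb3, 28.7 (4.23), Ccnd1 48.7 (4.00) and Sox4 29.2 (3.88). The lowest 5 at 48 h were Pou3f1 (-3.84), Pou3f2 (-3.25), Aqp3 (4.31, log2 ratio -3.23), Pou3f4 (-3.00) and Tex19.1 (18.7, log2 ratio -2.57). Against 0 h, the median of the proneural and neuronal list at 48 h was 2.18 on the log2 scale and lay above all random lists. That of the p53 list was -0.39 (percentile 0.615) and that of the oxidative stress list -0.73 (percentile 0.010). None of these ratios has a replicate check.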

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

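Chosen only after the results were seen were the tests of exchanged 0 h and 48 h libraries and of recovered reads, and the removal of the GC trend as such. Signal outside the genes analysed was found in 1 transcript row for a further placement and in 10 transcript rows without a gene symbol, each with a value of at least 10 in a library.

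Pou3f2 was lowest in the library labelled 48 h, together with Pou3f1 and Pou3f4. Shared reads between these paralogs are argued against, since at most 1.175% of the 36-base windows of Pou3f1 or Pou3f4 lay within 2 mismatches of Pou3f2. For Pou3f3 the share was 0.814%, and from 0 to 24 h its value was 0.0067 to 0.0145 of that of Pou3f2. Shared reads are therefore not excluded for Pou3f3. GC content as the whole source is argued against too, since with its trend removed the 0 h value of Pou3f2 was still 6.44 times the 48 h value (10.7 times before). An exchange of the 0 h and 48 h libraries is argued against by the 200 genes steepest from 2 to 24 h, of which 70.5% went the same way from 0 to 48 h. A single wrong label of the 48 h library, the counting of transgene reads and a fall of the POU genes in the cells stay open. The trend of Pou3f2 itself did not pass the test, and without the 48 h library its slope scaled to 48 h gave 0.10.

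Of 11 tested proneural and neuronal genes 4 rose with time, and the call of the list was lost at an adjusted p = 0.359 with an estimated correlation. GC content as the whole source is argued against by a median fitted change of 1.849 with its trend removed (1.94 before, 11 members). The median of 3.527 on recovered reads (26 members) does not decide about the length in the deposited unit, since the fits hold different members. A span divides a gene's value alike in every library, but low values then fall under the filter or are shrunk by the 1 added. Crmp1, with a span of 46.3 kb, had a fitted change of 2.11 in the main test and 5.15 on reads. Of 100 orders of the 7 libraries, the real one included, 4 gave the list an upward p as small as the real order (9.989e-10, with 9.857e-11 as the smallest of the others) and 4 called as many genes (23, with 557 as the highest of the others), a share close to the limit of 0.05. Orders that call many times the real number point to a structure of the samples: 3 orders called more than 100 genes, and at most 0 each with the GC trend removed, where 3 of 100 orders called as many as the real 13 and the highest other called 56. A response to Brn2 is a hypothesis that remains open beside differentiation from other sources, because Pou3f2 had no trend that passed the test and no unlit series was used here.

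FGF and ERK response genes had a median log2 ratio to 0 h of 0.61 at 2 h, and of 0.78, 0.77, 0.82 and 0.54 at 4, 6, 14 and 24 h, so the pattern sets the 0 h library against the later ones. For 2 h, GC content as the whole source is argued against by a median at percentile 99.99 of the random lists with its trend removed, and transcript length by percentile 99.99 with both trends removed. Genes of one pathway are regulated together, so random lists do not give the chance of such a median. A response to light, to handling or a change of medium and a property of the single 0 h library, which all these ratios share, stay open.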

How the results depend on the processing

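Chosen only after seeing the data were the GC and length removals, the fit without the 6 h and 48 h libraries, the other transcript row and limma-voom; the other alternatives were planned. The test found 19 genes rising and 4 falling. These counts were 1 and 0 with quantile normalization, 0 and 0 with no filter on low values (17842 genes tested, 3078 with an unadjusted p under 0.05), 36 and 7 with pseudocount 0.1, 0 and 0 with pseudocount 5, 43 and 12 with time as rank, and 162 and 28 with hours untransformed. With a mean of at least 10 there was 1 falling gene, and with 2 levels of time 26. With a library left out in turn the rising count ran from 1 to 54 and the falling count from 0 to 25: 54 and 25 without 0 h, 7 and 2 without 2 h, 1 and 0 without 4 h or 24 h, and 1 and 1 without 48 h. They were 0 and 0 without the 6 h and 48 h libraries, 11 and 2 with the GC trend removed, 9 and 1 with the GC and transcript length trends removed, 291 and 108 with limma-voom on recovered reads, and 323 and 54 with limma-voom and the GC trend removed. Fewer libraries and more or fewer genes tested change what can be called; for the others the cause was not tested.

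The Pou3f2 change of -1.95 was not called in any of 22 alternatives. It ran from -2.52 to 0.10 with a library left out in turn, turning sign without 48 h, and was 0.019 without the 6 h and 48 h libraries. Of lists, 7 were called up and 3 down. With a mean of at least 10, 0 were called up, and with an estimated correlation 0 up and 0 down. Called down were 8 without 0 h, 5 with the GC trend removed, 5 with the GC and length trends removed, and 5 with limma-voom and the GC trend removed. Without the 0 h library the test of ribosomal proteins (median -0.22, adjusted p = 0.005) and trophectoderm (median -0.79, adjusted p = 0.041) turned from upward, not called, to called down, though the trophectoderm median was already -0.10; with a library left out in turn their medians ran from -0.22 to 0.23 and from -0.79 to 0.18. Calls were kept in 23 of 24 alternatives for oxidative stress, 22 of 24 for p53, cholesterol and formative pluripotency, 22 of 23 for neuronal genes, 21 of 23 for histones, 20 of 24 for Notch, 16 of 24 for heat shock, 15 of 24 for neural progenitor and 12 of 24 for core pluripotency.

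Genes at least 2-fold higher and lower than at 0 h, in order of time from 2 h to 48 h, were 33 and 14, 15 and 3, 41 and 6, 30 and 21, 38 and 20, and 160 and 61 with pseudocount 5. They were 123 and 82, 79 and 25, 161 and 51, 146 and 135, 155 and 112, and 595 and 354 with a minimum value of 1, and 19 and 8, 9 and 1, 36 and 3, 9 and 10, 22 and 7, and 66 and 22 with a minimum value of 50. Against the mean of 0, 2 and 4 h, 36, 18 and 163 genes were higher at 14, 24 and 48 h. At 6 h and 48 h the counts were 47 and 5, and 154 and 42 with the GC trend removed, and 34 and 6, and 152 and 44 with both trends removed. A lower minimum lets in genes with few reads, and a higher pseudocount shrinks their ratios. Depth limits genes of low value, and with 1 library per time the spread could be judged only around the fitted trend.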

Other observations

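Genes of the p53 and oxidative stress lists had lower medians in the 14 h library than in the 6 h library, with 1 library each and no test. The median log2 ratio to 0 h of the p53 list was -0.23 at 2 h, 0.18 at 4 h, 0.24 at 6 h, -0.80 at 14 h and -0.66 at 24 h, and that of the oxidative stress list -0.31, 0.18, 0.24, -0.86 and -0.38. At 14 h both medians lay below all random lists matched on mean expression. Cholesterol biosynthesis genes had a median of 0.10 at 6 h and 0.68 at 14 h, above all random lists at 14 h. G2 and mitosis genes had medians of -0.37, -0.49 and -0.46 at 2, 4 and 6 h, below all random lists, -0.16 and -0.11 at 14 and 24 h, and -0.65 at 48 h, again below all random lists. With the GC trend removed these medians were -0.31, -0.45, -0.21, -0.03, -0.07 and -0.18 in order of time.

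Immediate early genes had median ratios to 0 h of 0.57, 0.58 and 0.53 at 2, 4 and 6 h. At 14, 24 and 48 h the ratios were 0.08, -0.12 and 0.30 (percentile 89.1 at 48 h). Glycolysis and hypoxia genes had medians between 0.38 and 0.61 at all 6 later times, and with the GC trend removed the 48 h median was 0.12 (percentile 50.7). The naive pluripotency list had its lowest median at 14 h, -0.29 (percentile 0.045), and stood at 0.24 at 48 h. These medians compare single libraries, each with the same 0 h library.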
